A study of Mus musculus with 6 samples.

How the data were processed

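Single-embryo bisulfite libraries were compared between 3 embryos injected with sperm small RNAs of normal mice and 3 injected with those of stress-induced depressed mice. Fertilised eggs were of C57BL/6 background, were cultured at 37 °C and were taken at embryonic day 4.5, and DNA of each was converted with bisulfite and primed at random to make its library, per the labels' protocols. Trim Galore 0.3.3, Bismark and SAMtools were used with the mouse build mm10, per the submitters' processing notes. The caller of the differentially methylated regions, its thresholds, its coverage filter and the way 3 embryos of a group were combined are not given in the sources used here.

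One table was deposited, the authors' list of regions that differ between depressed and normal. Per the file headers it gives position, length, number of cytosines, cytosine context, mean methylation of each group as a fraction between 0 and 1, their difference and a region statistic (a score that adds up along the region). The fractions were multiplied to percent here. The difference equalled the depressed minus the normal mean within 1e-09 in all 9707 regions, and in 2 regions the statistic had the opposite sign. The table has 18732 annotation entries, since a region is listed once for each gene, promoter, exon, intron, UTR, CpG island or repeat it touches. Entries were collapsed to 9707 distinct regions for every count of regions. Of these, 9680 lay on the primary chromosomes, 2 on the mitochondrial genome and 25 on scaffolds or patches. All listed regions carry at least 1 annotation entry, so regions outside annotated features were not analysed here. The smallest absolute difference was 2.00 percentage points, the smallest region 51 bp and the smallest number of cytosines 4. The smallest absolute statistic was 13.7 for CG, 15.3 for CHG and 307 for CHH regions.

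The deposited group means come without counts, coverage or values per embryo. The depth behind each level is unknown, no coverage minimum could be set, and no test between embryos, no leave-one-out and no split of the samples could be made. All intervals are exact binomial intervals over regions (95%) and describe the list, not the precision of a level. P-values over regions compare classes of regions in this list.

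The tests, the 20 gene lists and the rule for named genes were fixed before the data were examined. CG was the main context and CHG and CHH were given apart. Direction was the share of regions higher in the depressed group, with an exact two-sided sign test over chromosomes. Annotation classes were compared between higher and lower regions with Fisher's exact test, adjusted over 10 classes by the Benjamini-Hochberg method. Direction on chromosome X was compared with the autosomes by Fisher's exact test. Densities used the span from the chromosome start to the end of its last annotated gene in the RefSeq table for GRCm38 (mm10), since chromosome lengths were not at hand. The weight of chromosomes 9 and 10 was described after it had been seen.

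Gene lists were tested for the number of genes with a region, against 100000 random lists of the same size drawn from 21900 protein-coding genes and matched on gene length in 10 classes (two-sided permutation p, adjusted over 20 lists). Of 4040 gene names in the deposited table, 3981 matched a symbol or a unique synonym of the reference. Of 656 genes in the lists fixed by name, 633 were in the background. A test of direction used Fisher's exact test over genes with regions of 1 direction only. On simulated lists of 40 genes with no effect, the length-matched test gave p under 0.05 in 1.5% of lists for CG, 2.5% for CHG and 2.8% for CHH, and 10.5, 9.8 and 37.5% without matching. With odds of a region raised by a factor of 4, it recovered 53.5, 84.0 and 93.5% of lists. The simulated lists alternated between draws from all genes and draws from long genes only, and hits were drawn independently for each gene. The test treats genes as independent, which overlapping genes are not.

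Named genes in the CG context were, per direction, the 10 with the strongest absolute statistic in a promoter, UTR or exon, the 5 with the most regions, up to 4 members of each list, and the longest region; predicted genes were passed over in the first steps. Only 6 genes met the first step among higher CG regions, and Pcyt1b was named after its values were seen to complete the 9. Of the 10 lower CG genes of the first step, 9 are described. The rule was applied to CHG and CHH after the table had been seen, and the text names some of its genes. Counts of regions per gene were not adjusted for gene length. Fgfr2, which the rule picks by its number of regions, is not described, since 0 of its 20 listed regions lay within 10 kb of its RefSeq span. Of 6863 pairs of a gene and a region, 149 were over 10 kb apart, a distance chosen after the table had been seen. Alternatives covered the size of the difference, the number of cytosines, the statistic, the chromosomes used, the context, merging of regions within 1 kb, weighting, the background of genes and the way regions are assigned to genes.

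For the closing section, 8 lists of transcripts abundant in a tissue were written after the regions had been seen and before they were tested, and tested with the reference genes as a set of 9. Some neuronal genes already noticed were kept out, but Nefm and Nefl, both listed for the strongest CHG region, were not, so the test was repeated without them. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.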

Results

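The data came from 6 single mouse embryos at embryonic day 4.5, the late blastocyst stage, each sequenced on its own by whole-genome bisulfite sequencing. In this assay unmethylated cytosines are converted and read as thymine, while methylated cytosines are still read as cytosine. As fertilised eggs, the embryos had received small RNAs from sperm at 2 ng/µl by microinjection. The RNA came from normal males for 3 embryos (replicates 1, 2 and 4, the normal group) and from stress-induced depressed males for 3 embryos (replicates 1, 3 and 4, the depressed group). Embryos were collected about 108 h after injection. The design asks whether sperm small RNAs of depressed males leave another DNA methylation pattern in the embryo than those of normal males. The deposited table lists 9707 distinct differentially methylated regions between the groups in 3 cytosine contexts, where H stands for any base but G. For each region it gives the authors' mean level of each group and their region statistic. It holds 0 columns of values per embryo, so no value has a spread or a number of replicates of its own, and the read depth behind it is unknown. Tests across regions compare classes of regions within this list, not embryos, and whether a difference exceeds the spread between embryos could not be tested here.

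CG methylation, the usual form in mammals, was lower in the depressed group at nearly every listed CG region. Of 880 CG regions, 867 were lower and 13 were higher in the depressed group, so 1.48% were higher (95% exact interval 0.789 to 2.51%). In the regions listed as lower, the authors' mean had a median of 4.92% in the depressed group and 70.2% in the normal group. These regions were short, with a median of 117 bp and 5 CpGs. The 13 regions listed as higher had median levels of 74.4% in the depressed group and 15.3% in the normal group. On 20 chromosomes the lower regions outnumbered the higher ones and on 1 chromosome, X, the reverse held (exact sign test over chromosomes, two-sided, p = 2.1e-05). The same direction held for CHG regions and the opposite one for CHH regions, as given further on.

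**Figure D1:**
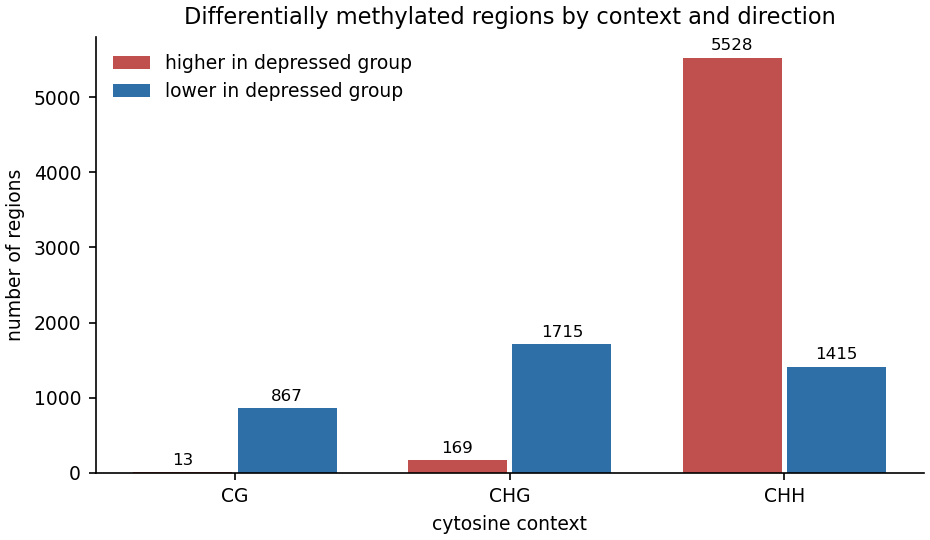
Number of regions in the authors' deposited table (vertical axis) by cytosine context (horizontal axis), with red bars for regions higher and blue bars for regions lower in the depressed group. CG and CHG regions were mostly lower (867 of 880 and 1715 of 1884), while 5528 of 6943 CHH regions were higher.

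Among regions listed with a named gene, the strongest CG statistics in promoters, untranslated regions (UTRs) or exons lay at Enah, which encodes a regulator of actin at the cell edge, and at Clptm1l, Agpat2, Ppp1r15b and Nptx1. At Enah (mm10, chromosome 1, 182019641 to 182019859; promoter, 5′ UTR and exon, 74 CpGs) the authors' mean was 0.933% in the depressed and 23.6% in the normal group. At Clptm1l (chromosome 13, 73604092 to 73604214; 5′ UTR and exon) the level was 0.852% in the depressed group against 16.3% in the normal group. Agpat2, an acyltransferase of phospholipid synthesis, had 1.03% against 13.7%, Ppp1r15b, a phosphatase subunit of the integrated stress response, 1.42% against 11.9%, and Nptx1, a neuronal pentraxin, 1.18% against 12.8%. Arih1, a ubiquitin ligase gene, had 2.49% in the depressed and 37.9% in the normal group at its promoter and 5′ UTR (chromosome 9, 59486219 to 59486407). Dusp7, a phosphatase gene of the MAP kinase pathway, had 2.14% against 18.0%, and Iffo2 had 1.27% against 9.69%. The exonic region of Lrp10 was at 20.7% in the depressed and 65.9% in the normal group. Of the 10 strongest regions, of which 9 are described here, 5 (among them those of Enah, Arih1, Dusp7 and Lrp10) overlapped a CHG or CHH region that was lower in the depressed group too, against 38 of the 272 lower CG regions in an exon or UTR (14.0%) and 41 of all 867 (4.73%).

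Ank3, which encodes the ankyrin that organises the axon initial segment, carried the most lower CG regions, with 9, a count not adjusted for gene length. Its strongest one (chromosome 10, 69993091 to 69993337; promoter, exon and intron) was at 19.03% in the depressed and 75.7% in the normal group. Lingo1, a receptor component that limits axon growth and myelination, carried 5 regions, the strongest at 1.21% against 76.7% in an intron. Sash1, the sodium-proton exchanger gene Slc9a9 and Thsd4 carried 4 each, the strongest at 6.99% against 70.0%, 2.34% against 85.0% and 12.8% against 74.9% in the authors' deposited table. The longest lower CG region lay in Csnk1g2, a casein kinase gene (chromosome 10, 80626741 to 80631971), at 4.71% in the depressed and 71.3% in the normal group, with only 5 CpGs in 5231 bp. Ank3, Lingo1, Sash1, Slc9a9, Thsd4 and Csnk1g2 all lie on chromosomes 9 or 10, where the CG regions were concentrated.

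Among the 13 CG regions higher in the depressed group, 9 were listed with a gene. The promoter of Crb2, which encodes an apical polarity protein (chromosome 2, 37775623 to 37775747), was at 77.8% in the depressed and 10.9% in the normal group. Hs6st2, a heparan sulfate sulfotransferase gene (chromosome X, 51680149 to 51680270; exon), had the strongest statistic with 53.7% against 6.41%, and Ppp1r3f, a gene for a glycogen-targeting phosphatase subunit, had 49.3% against 10.7% at its promoter and exon. Exonic regions of Tmtc2 (74.4% against 15.1%), Myo1a (52.7% against 31.1%) and Ano10 (51.1% against 30.9%) were higher as well, while Tmtc2 also carried 3 lower CG regions. An intron of Btbd9 stood at 79.0% against 23.4%, an intron of Pcyt1b at 84.5% against 19.02%, and an intronic endogenous retroviral repeat in Gabrg3, a GABA receptor subunit gene, at 71.3% against 22.4%. The other 4 regions were listed under repeats alone, with levels in the depressed group between 57.4 and 81.1%. On chromosome X, 4 CG regions were higher and 3 lower, against 9 higher and 860 lower on the autosomes (Fisher's exact test, two-sided, odds ratio 127, p = 1e-06), a test that rests on 7 regions. The embryos' sex is not given in the sources used here.

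**Figure D2:**
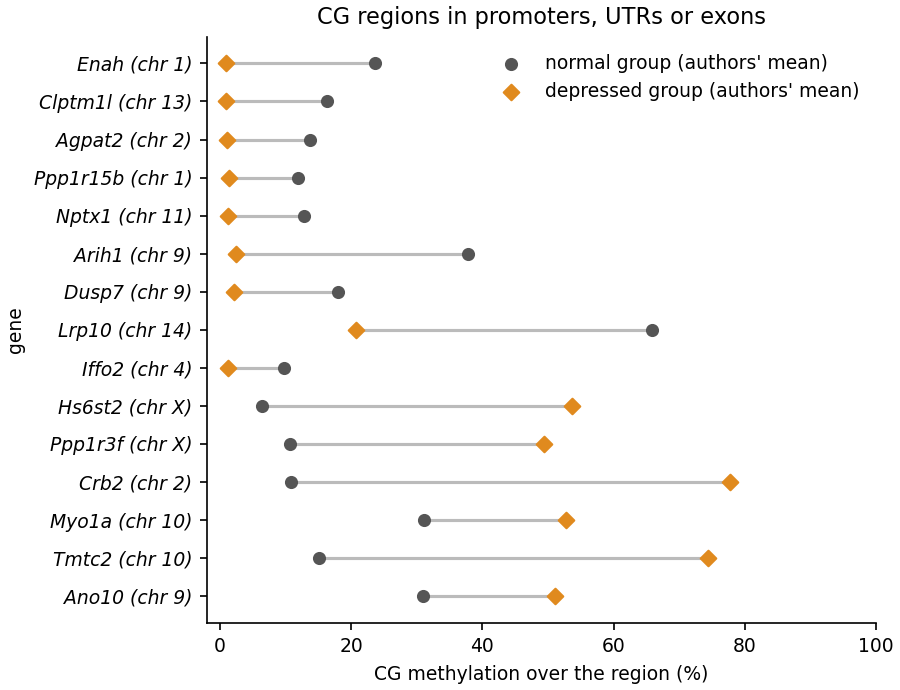
Authors' mean CG methylation in percent (horizontal axis) of the normal group (grey circles) and the depressed group (orange diamonds) for the genes with the strongest CG statistic in a promoter, UTR or exon (vertical axis, with chromosome). The 9 upper genes were lower in the depressed group, as Enah with 0.933% against 23.6%, and the 6 bottom genes were higher, as Crb2 with 77.8% against 10.9%; no spread between embryos can be drawn.

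Chromosomes 9 and 10 held most of the lower CG regions. With 268 lower regions on chromosome 9 and 239 on chromosome 10, they carried 507 of the 867 (58.5%, 95% exact interval 55.1 to 61.8%), while they hold 10.1% of protein-coding genes. Per Mb of annotated span there were 2.16 CG regions on chromosome 9 and 1.85 on chromosome 10, against a median of 0.136 on the 17 other autosomes (0.0167 to 0.516, highest on chromosome 2). All 52 windows of 5 Mb on these chromosomes held a lower CG region. The levels were like those elsewhere, with medians of 4.96% in the depressed and 72.4% in the normal group on chromosomes 9 and 10 and of 4.88% and 67.7% on the other chromosomes. Regions of the other contexts showed no such concentration, with 10.3% of the lower CHG regions, 11.4% of the lower CHH regions and 9.91% of the higher CHH regions on these chromosomes. No p-value is given for this concentration, since neighbouring regions are not independent and its units are chromosomes.

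**Figure D3:**
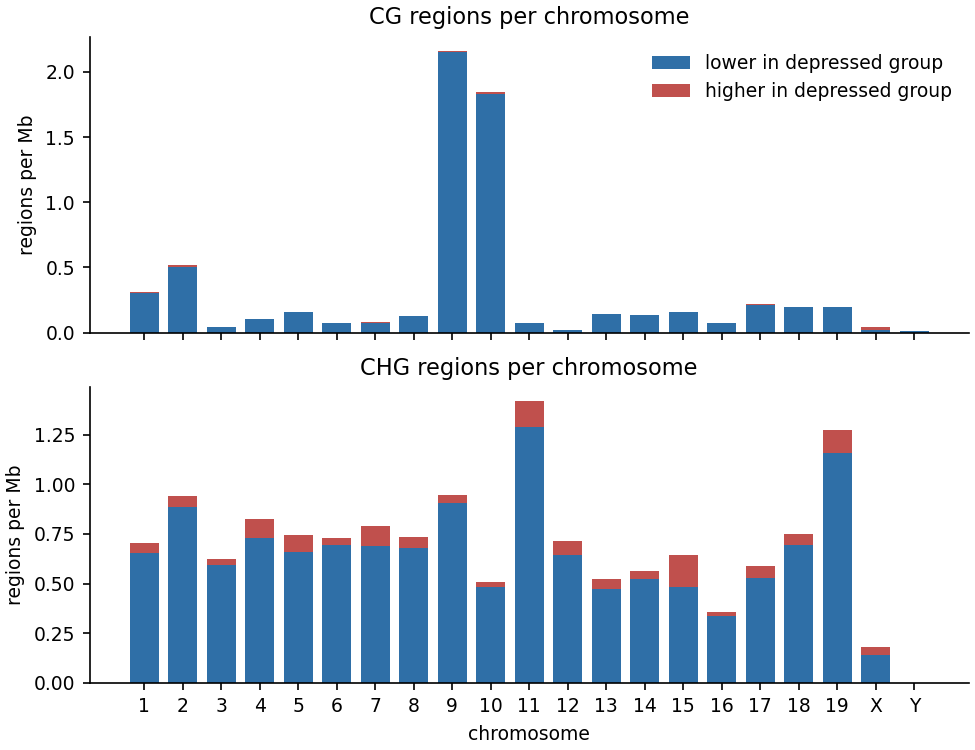
Regions per Mb of annotated span (vertical axes) on each chromosome (horizontal axis) for CG regions (top) and CHG regions (bottom), with blue for regions lower and red for regions higher in the depressed group. CG regions reached 2.16 per Mb on chromosome 9 and 1.85 on chromosome 10 and at most 0.516 on the other autosomes.

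Only regions with an annotation entry were listed, so shares inside genes leave out unannotated sequence. Within that limit, most lower CG regions lay inside genes. Introns were listed for 68.4% of them, exons for 31.1%, promoters for 13.03%, CpG islands for 2.999% and repeats for 43.8%. The lower regions were listed with 569 genes, 84 of them at the promoter. Of 10 annotation classes, 0 differed between higher and lower CG regions by Fisher's exact test with Benjamini-Hochberg adjustment, and 0 at an unadjusted p under 0.05. With 13 regions on the higher side, differences in class could be seen only if large.

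The fixed gene groups related to the brain each had few members with a CG region, nearly all lower in the depressed group. Among synaptic adhesion genes these were 3 of 51, Ntm (1.32% in the depressed against 75.3% in the normal group), Cadm1 (11.6% against 79.1%) and Dscaml1 (10.5% against 74.3%). Axon guidance genes also had 3 of 70, the semaphorin receptor gene Plxnc1 (6.65% against 77.9%), the ephrin receptor gene Ephb1 (6.196% against 76.1%) and Ntng2 (16.9% against 78.6%). For voltage-gated calcium channels 3 of 26 genes had one, namely Cacna1s (9.98% against 66.1%), Cacna2d2 (12.5% against 78.1%) and Cacna1g (4.61% against 53.3%). The serotonin receptor gene Htr3b (3.796% against 78.4%) was the only monoamine gene of 41, Grik4 (1.46% against 79.6%) the only glutamate receptor gene of 26, and Gabrg3, higher in the depressed group, the only GABA gene of 30. None of these 6 groups held more or fewer genes with a CG region than random lists matched on gene length (permutation test, each adjusted p = 1). All but Ntng2, Cacna1s, Cacna1g and Gabrg3 lie on chromosomes 9 or 10, and without these chromosomes 0 of 51 synaptic adhesion, 0 of 41 monoamine, 0 of 26 glutamate receptor and 1 of 70 axon guidance genes had a CG region.

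Groups tied to early development and to the machinery of methylation showed as few. The Wnt pathway had 3 of 60 genes, the kinase gene Gsk3b in its 3′ UTR (13.1% against 58.3%), Apc2 (17.2% against 75.5%), where a lower CHG region overlapped, and Sfrp1 (2.22% against 46.7%). Trappc9 (7.002% against 64.9%, intron) was the only 1 of 72 imprinted genes, Mbd3, a subunit gene of the NuRD repressor complex (6.27% against 69.7%), the only 1 of 31 genes of methylation writers, erasers and imprint protection, and Ago2, the slicing Argonaute (13.7% against 55.7%), the only 1 of 30 small RNA pathway genes. Of the ubiquitously expressed reference genes, Actb (4.17% against 64.7%) and Eef2 (9.74% against 61.3%) had a CG region, and both overlapped lower regions of other contexts. No gene of the pluripotency, trophectoderm, primitive endoderm, stress hormone, neurotrophin, germline or Hox lists had a CG region. For the groups of this paragraph the adjusted p of the permutation test lay between 0.876 and 1.

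Clustered protocadherins, the cell-surface proteins that give neurons their identity, were the 1 group with more genes than random lists, 11 of 57 against 2.57 (permutation test, adjusted p = 0.0028). All 11 alpha genes, Pcdha1 to Pcdha4 among them, were listed for 1 region in a shared intron (chromosome 18, 37038169 to 37038276, 7 CpGs), at 2.78% in the depressed and 67.7% in the normal group. The group's count thus rests on 1 region, and 0 groups passed when each region was counted for 1 gene. Olfactory and vomeronasal receptors had 0 of 1463 genes against 5.97 (permutation test, adjusted p = 0.0268), a call lost in most other settings, such as without chromosomes 9 and 10 (2.23, adjusted p = 1), with all genes as background (3.67, adjusted p = 0.299) or with midpoints inside the gene (4.40, adjusted p = 0.221). Of the 20 lists, 0 differed from other genes in the direction of their CG regions by Fisher's exact test after adjustment, and 1 did at an unadjusted p under 0.05.

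CHG methylation, which is scarce in most mammalian cells, was lower in the depressed group at 1715 of 1884 regions and higher at 169, so 8.97% were higher (95% exact interval 7.72 to 10.4%). The lower regions had a median of 0.174% in the depressed and 30.9% in the normal group. In promoters, UTRs or exons, with predicted genes passed over, the strongest lay in the neurofilament gene Nefl (chromosome 14, 68083984 to 68084811, 3.17% against 30.2%), a region also listed for Nefm, whose RefSeq span is over 10 kb away, in Trim8 (1.49% against 28.2%), in the neuropeptide precursor gene Vgf (0.346% against 44.7%) and in Map1a, a microtubule-associated protein gene of neurons (0.468% against 38.9%). Enc1 (0.739% against 82.0%), Nsg2 (0.0815% against 76.7%), Ppp2r2c (0.649% against 62.0%), Cdk5r2 (0.450% against 51.2%) and Actb (1.58% against 50.7%) followed. In Grin2b, an NMDA receptor subunit gene with 6 lower CHG regions, the strongest was at 0.0610% against 58.0%. Among higher CHG regions, the strongest statistics by the same rule lay in Sfi1 (6.81% in the depressed against 0.335% in the normal group), Hsdl2 (39.4% against 0.159%) and Repin1 (11.2% against 0.268%). Lower regions outnumbered higher ones on 20 of 20 chromosomes (exact sign test, two-sided, p = 1.91e-06).

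Exons and UTRs held 1425 of the 1715 lower CHG regions (83.1%), and 146 of the 169 higher ones (86.4%), against 272 of the 867 lower CG regions (31.4%). The 3′ UTR was listed for 47.7% of lower and 13.6% of higher CHG regions (Fisher's exact test, adjusted p = 2.71e-18), and CpG islands for 11.1% of lower and 23.1% of higher ones (adjusted p = 0.000165). The test treated regions as independent, though some genes carried several lower CHG regions. Reference genes such as Ywhaz (0.0759% against 73.4%) and Tubb5 (1.17% against 58.4%) were over-represented, 9 of 30 with a CHG region against 1.57 in length-matched random lists (permutation test, adjusted p = 0.000267). Hox genes had 7 of 39 against 1.97 (permutation test, adjusted p = 0.031), among them Hoxa11 (0.879% against 9.59%) and, higher in the depressed group, Hoxd10 (20.9% against 1.01%). The Hox list did not pass for lower (5 against 1.73, adjusted p = 0.158) or higher regions alone (2 against 0.245, adjusted p = 0.335), nor with regions within 10 kb of the RefSeq gene (6 against 1.95, adjusted p = 0.112), by permutation test. Clustered protocadherins had 32 of 57 genes against 6.11, all from 5 distinct regions, 2 higher over alpha genes and 3 lower over beta or gamma genes, and olfactory and vomeronasal receptors had 2 of 1463 against 24.1 (each adjusted p = 0.0002, from the smallest p these permutations can give). In a list of 60 abundant neuronal transcripts drawn up after the table had been seen, 36 genes had a lower CHG region in an exon or UTR.

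CHH regions that were lower in the depressed group resembled the CHG regions. There were 1415 of them, with medians of 0.637% in the depressed and 24.9% in the normal group, 65.9% in an exon or UTR. Of these regions 768 overlapped a CHG region, all in the same direction. The neuronal calcium sensor gene Hpcal4 (chromosome 4, 123192521 to 123194436, 0.708% against 52.5%), the pair Vgf and Ap1s1, which share a region (0.801% against 32.9%), the cofilin gene Cfl1 (0.312% against 88.0%) and Map1a (0.687% against 59.8%) had the strongest statistics in nuclear genes by the same rule. A mitochondrial region over mt-Co1 ranked among them with 0.889% against 5.89%. Bsn, a scaffold gene of the presynaptic active zone (1.03% against 23.8%), Celf2, Grin2b and Mapk8ip3 carried 4 lower regions each. Celf2 also carried 5 higher CHH regions and Grin2b 4, while Bsn and Mapk8ip3 carried 0. In the same list of 60 neuronal transcripts, 30 genes had a lower CHH region in an exon or UTR, against 2.87 in length-matched random lists (permutation test, adjusted p = 0.00018). Of 30 reference genes 6 had one (0.893 in random lists, permutation test, adjusted p = 0.00207). The counts were 0 of 38 liver (1.30), 0 of 31 blood (0.843) and 0 of 35 testis genes (0.948), which did not differ from random lists.

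CHH regions higher in the depressed group were the largest class, 5528 of 6943 regions (79.6%, 95% exact interval 78.7 to 80.6%), and their differences were small. Their median levels were 4.76% in the depressed and 0.769% in the normal group, over 88 cytosines. Nrg1, which encodes the growth factor neuregulin, carried 13 such regions, the strongest at 4.21% against 1.05% in an intron, and the alpha-catenin gene Ctnna2 carried 11 (strongest 6.49% against 1.35%). Lrp1b carried 9 and Cntnap2 carried 8, and these counts were not adjusted for gene length. At promoters, Rac2 stood at 29.3% against 0.309%, Olfr723 at 5.46% against 1.35% and Aldh1a3, a retinoic acid synthesis gene, at 9.59% against 2.27%. On all 21 chromosomes higher CHH regions outnumbered lower ones (exact sign test, two-sided, p = 9.54e-07). Among CHH regions that differed by at least 10 percentage points, however, 515 were higher and 1094 lower (32.0% higher).

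The 10 annotation classes all differed between higher and lower CHH regions (Fisher's exact test with regions treated as independent, largest adjusted p = 1.45e-10). Exons were listed for 2.01% of higher and 65.9% of lower regions, repeats for 62.6% and 27.5%. The repeat family IMPB_01 accounted for 759 higher regions (13.7%), with medians of 5.19% in the depressed and 0.876% in the normal group, and the retroviral repeat RLTR31D_MM for 355 (4.96% against 0.710%). Of the 20 gene lists, 0 held more or fewer genes with a CHH region than length-matched random lists after adjustment, and 6 did at an unadjusted p under 0.05. Direction, in contrast, differed from other genes for 4 lists. Olfactory and vomeronasal receptors with CHH regions of 1 direction had 40 higher and 1 lower (adjusted p = 1.02e-05), imprinted genes 6 higher and 13 lower (adjusted p = 0.0169), reference genes 0 higher and 6 lower (adjusted p = 0.0124), and clustered protocadherins 0 higher and 12 lower (adjusted p = 3.39e-05), all by Fisher's exact test over genes. The protocadherin count rests on 2 lower regions, and leaves out 9 genes that carry 1 higher region beside a lower one.

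**Figure D4:**
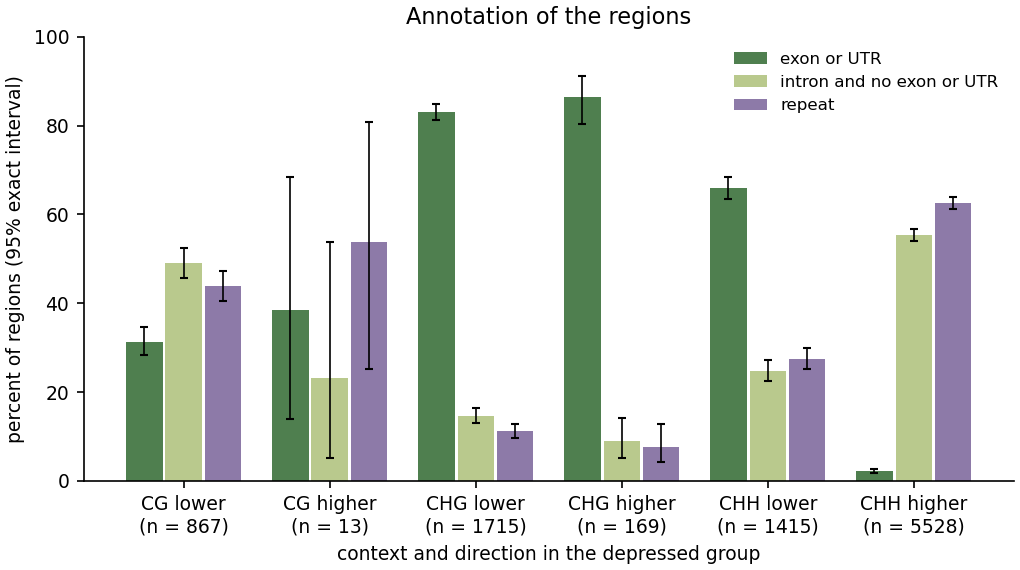
Percent of regions (vertical axis) listed under an exon or UTR, under an intron and no exon or UTR, or under a repeat, by cytosine context and direction in the depressed group (horizontal axis, n is the number of regions). Error bars are 95% exact binomial intervals over regions; exons or UTRs held 83.1% of lower CHG and 65.9% of lower CHH regions but 2.23% of higher CHH regions.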

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

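The settings that leave out chromosomes 9 and 10, long regions, differences under 10 percentage points, the chromosome 17 and mitochondrial regions or CG regions overlapping other contexts, that count each region for 1 gene or only genes within 10 kb of it, that move the chromosome comparison to other contexts, or that take an unweighted mean of the differences were chosen after the results were seen. Merging regions within 1 kb was planned for direction, but for the chromosome comparison it was chosen after the results were seen. Of 73 alternatives for 9 results, 54 gave the same direction and the same side of the threshold. The share of higher CG regions stayed between 0.682 and 2.70% in every CG setting, but was reversed in the CHH context (79.6%). The share of higher CHH regions was reversed to 32.0% among regions that differ by at least 10 percentage points, which follows from their many small differences. The median difference of lower CG regions, -64.2 percentage points, was -62.3 as an unweighted mean and -64.3 as a mean weighted by length, and moved to -50.5 as a mean weighted by cytosines. The density of chromosomes 9 and 10 over the other autosomes, 14.7-fold for CG, was 0.997 for CHG and 1.01 for CHH regions.

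Annotation classes that differ by direction were 0 for CG, 2 for CHG and 10 for CHH. Gene lists passing the enrichment test were 2 for CG and 4 for CHG. The number was 1, the protocadherins, for CG regions with a difference, a number of cytosines or a statistic at or above the median, with all genes as background, with midpoints inside the gene, and without chromosomes 9 and 10. It was 0 in the CHH context, with promoters, UTRs and exons only, and with each region counted for 1 gene. Fewer regions remained in the filtered settings, and the cause was not tested. Lists differing in direction were 0 for CG, 1 for CHG and 4 for CHH. Of the 16 CG genes picked by statistic, 1 had a difference at or above the median, and 14 lay in the larger part by statistic.

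No paired analysis was possible because the deposited table gives group means only. Leaving out embryos, a coverage minimum, other splits of the samples and a background of genes near CpG-dense promoters were not run, the first 3 for the same reason and the last for lack of a table of such promoters. What depth limits cannot be stated, as no coverage is given.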

Other observations

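The tests of gene lists by direction and those on chromosomes 9 and 10, on introns, on transcript lists in higher CHG, in CHH and in CG regions, without Nefm and Nefl, within 10 kb of the RefSeq gene and on subsets and levels of CHH regions were chosen after the results were seen, while the tests of transcript lists in lower CHG regions and of cytosine density were set down before they were run, though the exonic pattern was known. Imprinted genes were over-represented among lower CHH regions, 14 of 72 genes against 5.17 in length-matched random lists (permutation test, adjusted p = 0.0037), but not among CG regions or lower CHG regions (12 of 72, adjusted p = 0.108). Of the other lists, 3 also passed among lower CHH regions by permutation test: reference genes with 6 of 30 against 1.06 (adjusted p = 0.0037), clustered protocadherins with 21 of 57 against 5.04, from 2 regions, and olfactory and vomeronasal receptors with fewer, 1 of 1463 against 16.5 (each adjusted p = 0.0002). Among higher CHH regions these receptors had more, 40 against 25.6 (permutation test, adjusted p = 0.0332). The imprinted genes include Peg3 (0.482% in the depressed and 27.8% in the normal group, 3′ UTR), Nnat and Blcap, which share a region (0.239% against 29.9%), and Bcl2l1 (1.47% against 81.3%), in exons or 3′ UTRs except for Blcap. Whether the call for imprinted genes is separate from the exonic and UTR pattern of lower CHH regions was not tested. In exons and UTRs, abundant neuronal and astrocyte transcripts were over-represented among lower CHH regions too. The neuronal list had 30 of 60 genes against 2.87 (permutation test, adjusted p = 0.00018). The astrocyte list had 6 of 26 genes against 1.04 (permutation test, adjusted p = 0.00258). The oligodendrocyte list did not pass, with 3 of 24 genes against 0.899 (permutation test, adjusted p = 0.267). Genes of the first lineages of the embryo had regions outside the CG context. Of 25 trophectoderm genes 8 had a CHH region, against 3.33 in random lists (permutation test, p = 0.0159, adjusted p = 0.0826), and 7 against 3.24 when only regions within 10 kb of the RefSeq gene count (adjusted p = 0.141). Of 22 primitive endoderm genes 5 had a CHH region, against 5.06 in random lists, and their direction, 5 higher and 0 lower, did not pass against 1778 higher and 966 lower among other genes (Fisher's exact test, adjusted p = 0.483). The pluripotency factor gene Sox2 had an exonic CHG region at 0.749% against 62.3%, the trophectoderm factor gene Cdx2 a CHG region at 15.6% in the depressed against 0.0364% in the normal group, and Dnmt3l, a cofactor gene of DNA methyltransferases, one at 8.51% against 0.119%. In the stress hormone axis, Adcyap1r1 (0.187% against 33.5%), Hsd11b2 (0.348% against 21.0%) and Tsc22d3 (0.0824% against 54.8%) had lower CHG regions in exons and 3′ UTRs, 3 of 35 genes with 2.37 in random lists (permutation test, adjusted p = 1).

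The strongest CG and CHH statistics of the table fell in 1 interval of chromosome 17 listed with no gene name. Its CG region (39843015 to 39846346, 747 CpGs) was at 1.95% in the depressed and 15.3% in the normal group, and its CHH region (39843029 to 39848112) at 0.823% against 7.38%. On the mitochondrial genome the CHG region from 5848 to 6112 was at 0.668% against 4.11%. The Y chromosome was listed with 161 higher CHH regions, 1 lower CHH region and 1 lower CG region. Outside genes, 4 higher CG regions lay in repeats alone, of the families L1MdA_III, L1MdN_I, IAPEy-int and L1MdA_IV.

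Lower CG regions concentrated on chromosomes 9 and 10. More genes there do not account for it, as the share of lower CG regions was 5.81 times that of protein-coding genes, and neither does a conversion difference on these chromosomes, since only 10.3% of lower CHG regions lay there. A few clustered loci are argued against by the spread, with 26.2% of the regions in the 5 fullest windows of 5 Mb. The depressed mean lay below the normal mean divided by 3 at 502 of the 507 regions (99.0%; median 4.96%, upper quartile 9.24%). If the 3 embryos weigh alike in the mean, a low level in only 1 or 2 of them would not give this. The regions were listed for their difference between the groups, however, which favours low depressed means, so this cannot settle it. Copy number or depth, of whole chromosomes or at single regions, may also let single embryos outweigh the others. That cannot be told apart from a loss shared by all 3 embryos, because there are 0 columns of values per embryo and the way embryos were combined is not given. An effect of the injected RNA on these chromosomes stays open as untested.

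Lower CHG regions lay mostly in exons and UTRs, with the 3′ UTR listed for 47.7% of them against 13.6% of higher CHG regions. Of 9 lists of abundant transcripts, 4 were over-represented among genes with exonic or UTR lower CHG regions at matched gene length: 36 of 60 neuronal (4.04 in random lists, permutation test, adjusted p = 9e-05, from the smallest p these permutations can give; without Nefm and Nefl, which the rule for named genes picks, 34 of 58 against 3.96), 10 of 26 astrocyte (1.43, adjusted p = 9e-05), 5 of 24 oligodendrocyte (1.22, adjusted p = 0.0276) and 9 of 30 reference genes (1.22, adjusted p = 0.00024), against 0 of 35 testis, 0 of 31 blood, 1 of 38 liver, 1 of 38 muscle and 2 of 35 oocyte and early embryo genes, with 1 neuronal gene also in the last list, while among higher CHG regions 1 of 60 neuronal (adjusted p = 1) and 3 of 38 liver genes (0.241, adjusted p = 0.0306) had one. Unconverted copies of messenger RNA in the normal group's libraries, read as methylated cytosines, may account for these lists as a hypothesis. Such copies would carry CG cytosines too. Among genes with exonic or UTR lower CG regions, 0 of the 9 lists passed the permutation test (neuronal 1 of 60 against 0.768, adjusted p = 1, and reference genes 2 of 30 against 0.263, adjusted p = 0.25). An unadjusted p under 0.05 was seen for 1 list (muscle, 3 of 38 against 0.388). With at most 0.768 genes expected per list, only a large excess could pass. Of exonic or UTR lower CHG regions in CpG islands, 14 of 178 overlapped a lower CG region. Counted from the CG side, 5 of the 10 strongest lower regions in a promoter, UTR or exon overlapped a lower CHG or CHH region. Of all 272 lower CG regions in an exon or UTR, 38 did. RNA copies thus cannot be told apart from other explanations without CG levels outside the listed regions. Genomic DNA of other cells or a change along whole genes cannot be told apart either, since the 14.6% of lower CHG regions in introns alone lies below the 49.1% of lower CG regions, but higher CHG regions also had only 8.88% there, and the table does not show how many introns could be called. Of neuronal genes 60.0% were hit, against 2.63% of liver genes. The testis, blood, liver, muscle and oocyte and early embryo lists did not differ from random lists, which held 1.15 to 1.86 genes. Lower CHG regions had like cytosine density in exons or UTRs and elsewhere, with medians of 8.33 and 8.44 cytosines per 100 bp. These values cannot settle incomplete conversion by cytosine density alone, since the densities cover listed regions only. The lists, too, were matched on gene length and not on cytosine density. Brain tissue as a source, for which the labels' protocols name no step that removes RNA, and a biological difference between the groups stay open as untested.

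Higher CHH regions were many, cytosine-dense (50.0 cytosines per 100 bp) and differed little. A uniform shortfall of conversion across the depressed group's libraries is argued against by its level in lower CHH regions, with a median of 0.637% and an upper quartile of 1.08%, below the median excess of 3.81 percentage points in the higher ones, but a shortfall confined to cytosine-dense stretches was not tested. Reads shared between copies of annotated repeats are not the whole cause, as 66.8% of CHH regions with no repeat entry were still higher. A region with no repeat entry need not be unique sequence, so reads shared between other copies cannot be excluded. Whether a region statistic that adds over cytosines admits such small differences cannot be told apart from a real excess, since the 32.0% of higher regions among those that differ by at least 10 percentage points is tied to leaving out small differences. Whether the small differences exceed the spread between embryos stays open.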
